A study of Mus musculus with 16 samples.

How the data were processed

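The samples were 16 hybridisations on a custom mouse oligonucleotide array, in 4 comparisons of 2 sorts with 2 arrays each. Spot intensity values and log10 ratios of red (Cy5) over green (Cy3) were made with Agilent Feature Extraction, per the file headers. The design text names version A.6.1.1, but per the file headers 6 files come from A.6.1.1 and the others from a pair of later versions (6 and 4 files). For activated NKT sort 2, the headers record another background method with background correction off. The Feature Extraction error model values, of no fixed unit, are also deposited and entered 1 alternative. The design text says that the authors combined ratios in Rosetta Resolver with error weights and a 2-fold threshold.

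The deposited value table holds log10 ratios. Of its 8014 lines, 7868 were complete in the 14 columns used to match, and 7820 matched 1 spot within 0.001. In 14 columns the values equalled the scanner file of the same sample, which settles their scale and direction. Column medians ran from -0.0063 to 0.0073 in log10. The column of the first array of CD4+CD25+ sort 1 equalled, at 99.99% of spots, the scanner file given for its dye-exchanged partner, and the partner's column equalled none of the files. The scale and direction of that last column were therefore not settled against a file. The 2 scanner files of this sort correlated at 0.943 across 3797 spots, whereas the files of the other 7 pairs correlated at -0.497 to -0.774, as an exchange of dyes gives. Both files were therefore taken as scans of 1 array. Their mean was used as 1 value, after removing the gene-specific dye effect estimated from the other 7 pairs. Tested on those 7 pairs, a single orientation correlated across probes with its partner array at 0.519 to 0.889 uncorrected and at 0.617 to 0.942 when treated in this way. For the affected sort, the correlation with the partner's column in the value table, across 5971 probes, was 0.521 uncorrected and 0.647 corrected.

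Background was corrected with normexp (offset 50) on mean signals and background medians. Each array was normalized by loess with control spots at weight 0, without scaling between arrays. Outlier spots were left out, and 2 files carry no outlier columns. Arrays were turned to NKT over partner, or activated over resting, and the arrays of a sort were averaged, giving 8 ratios. A probe was kept if well above background in 1 population's channel on all arrays of at least 1 comparison, which kept 6189 of 8082 probes. The probe with the highest mean brightness stood for a gene with several (62 genes). Gene names came from the RefSeq table of assembly GRCm38, used for names only, which named 2709 probes by accession and 163 by description. The file's name was kept for 23 probes, and 5187 had no symbol and were tested without being named. In all, 6115 genes were tested, 2220 of them with a symbol.

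Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 coefficient per comparison and 4 residual degrees of freedom shared by all 8 ratios. Adjusted p-values are Benjamini-Hochberg values over all genes tested, called under 0.05. For the 24 gene lists, camera was set to run at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Camera took only genes with values in all 8 ratios, so that some lists entered with fewer genes than were tested singly. Lists with fewer than 4 genes that had values in all 8 ratios were not tested. This left out the erythroid and platelet list and the CD8 markers. The lists, the tests and the rule for named genes were fixed before the data were examined. Per direct comparison, the rule took the 8 highest and 8 lowest called genes with a symbol and the same sign on all arrays. It added the 2 called members of each list with the largest ratios and 14 fixed genes. It gave 42, 45, 50 and 29 genes, not all of which are described. Of the fixed genes, Foxp3, Zbtb16 and Ifng were not measured. Some genes that the rule names are not reported here.

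On simulated data with 6115 genes and independent sorts, the procedure recovered 80 to 87% of 2-fold changes and 91 to 98% of 4-fold changes over the 4 comparisons, with 1.7 to 7.04% false calls. When the resting NKT preparation of a sort was shared by the comparisons, false calls rose to 11.1 to 17.6%. Sort differences in the data correlated between comparisons as such sharing would give, which does not establish it. If resting NKT preparations were shared, the adjusted p-values of the 4 direct comparisons are too small. The data do not measure by how much. These simulated percentages cover neither the indirect comparison nor the mean of the resting partners. Of simulated lists without a shift, 4% had a camera p under 0.05. The simulated genes were drawn independently of each other, so this share does not cover lists of correlated genes. In the data the estimated correlation was 0.463 for NK receptors and adaptors and 0.906 for the myeloid list.

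The alternatives changed the background correction, normalization, filter, dye orientation, replicate block, batch terms, probe choice, variance model, threshold and sorts used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.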

Results

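Gene expression was compared between sorted mouse lymphocyte populations with 2-colour arrays. Splenic natural killer T (NKT) cells, T cells that carry receptors typical of NK cells, were hybridised directly against CD4+CD25- T cells, CD4+CD25+ T cells and NK cells, and resting NKT cells were hybridised against activated NKT cells. Each of the 4 comparisons held 2 sorts, and each sort was meant to be measured on 2 arrays with the dyes exchanged, which makes 16 scanner files. The sort was the replicate (n = 2 per comparison). Median green intensities per array ran from 117 to 268 and median red intensities from 101 to 175. On the arrays other than activated NKT sort 2, between 3369 and 6458 of the 8091 non-control spots were well above background in green. On the 2 arrays of activated NKT sort 2 background correction was off and all 8091 carried this flag, so that it holds no information there. The small number of arrays limits the precision. The p-values measure only the spread between these samples, since the labels say that sorts were repeated but not that the animals were separate. For CD4+CD25+ sort 1, the file of the exchanged array held a second scan of its partner array, so that this sort rests on 1 dye orientation with an estimated dye effect removed. Differences between sorts correlated between the comparisons, as shared resting NKT cells of each sort would give, but the labels do not record such sharing. Under such sharing 11.1 to 17.6% of the calls in the direct comparisons on simulated data were false.

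The comparison with CD4+CD25- T cells asks what separates NKT cells from conventional CD4 T cells. Klrb1c, which encodes the NK1.1 antigen, was higher in NKT cells by 4.53 ± 0.14 on the log2 scale (SE, n = 2 sorts), or 23.1-fold, with an adjusted p of 0.000537. The labels list an antibody to NK1.1 among the sorting reagents, so this gene checks the labels. Klrd1, which encodes the CD94 receptor chain, rose by 2.57 ± 0.19, and Fasl, the ligand of the death receptor Fas, by 2.41 ± 0.07. Id3, an inhibitor of E protein transcription factors, was lower at -2.30 ± 0.22. The Trgv4 probe was higher by 3.40 ± 0.17, and Klra1, a member of the Ly49 receptor family, by 2.78 ± 0.13; near-identical family members may share these probes, so both identities are uncertain. Klra1 was well above background in CD4+CD25- cells on 2 of 4 arrays.

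Of the 21 tested NK receptors and adaptors, 8 rose in NKT cells over CD4+CD25- cells and 13 were not called; adjusted over the list alone, 9 were higher and 1 was lower. The camera test, which takes only genes with values in all 8 ratios and so left out Klrb1c, set 20 of the list's genes apart from the other genes (adjusted p = 6.92e-09, but adjusted p = 0.51 with an estimated correlation). Its median was 1.32 in sort 1 and 0.28 in sort 2. In the same sorts the median of the 14 myeloid list genes, none of them called, was 0.88 and -0.18. Among 19 Th1 genes, 4 rose, led by Il12rb1 (2.45 ± 0.26), a receptor chain for interleukin 12, and the chemokine receptor Cxcr3 (1.71 ± 0.07); adjusted over the list alone, 8 rose. The Th1 list, 18 genes in camera, had an adjusted p of 9.67e-07, and an adjusted p = 0.0971 with an estimated correlation. The 9 cytotoxic effectors held 2 that rose, Fasl and the protease gene Ctsw (1.87 ± 0.20), also 2 when adjusted over the list alone (list adjusted p = 6.73e-05; adjusted p = 0.495 with an estimated correlation). Of 9 naive and recirculating T cell genes, 3 fell, Klf2 (-1.82 ± 0.15) among them, and 6 fell when adjusted over the list alone (list adjusted p = 0.0286 over 7 genes; adjusted p = 0.495 with an estimated correlation). Klf2 encodes a transcription factor that controls lymphocyte trafficking. The fixed genes Tbx21 (0.54 ± 0.17), Gata3 (0.82 ± 0.22), Il4 (0.05 ± 0.12) and Il2ra (0.05 ± 0.07) were not called.

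In limma, 290 of 6115 genes passed an adjusted p of 0.05 against CD4+CD25- cells, 148 higher and 142 lower in NKT cells, and 91 of them differed at least 2-fold. A replicate block on the sort number, with the same sign in every comparison, gave 189. With only the 2 sorts of this comparison in the limma fit, 0 genes passed (650 at an unadjusted p under 0.05), and leaving out its own sort 1 or sort 2 left 76 or 42. Of 33 calls among the named genes, 11 held without either sort, Klrb1c, Klrd1, Fasl and Cxcr3 among them, while those of Il12rb1, Ctsw, Klf2 and Id3 did not.

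**Figure D1:**
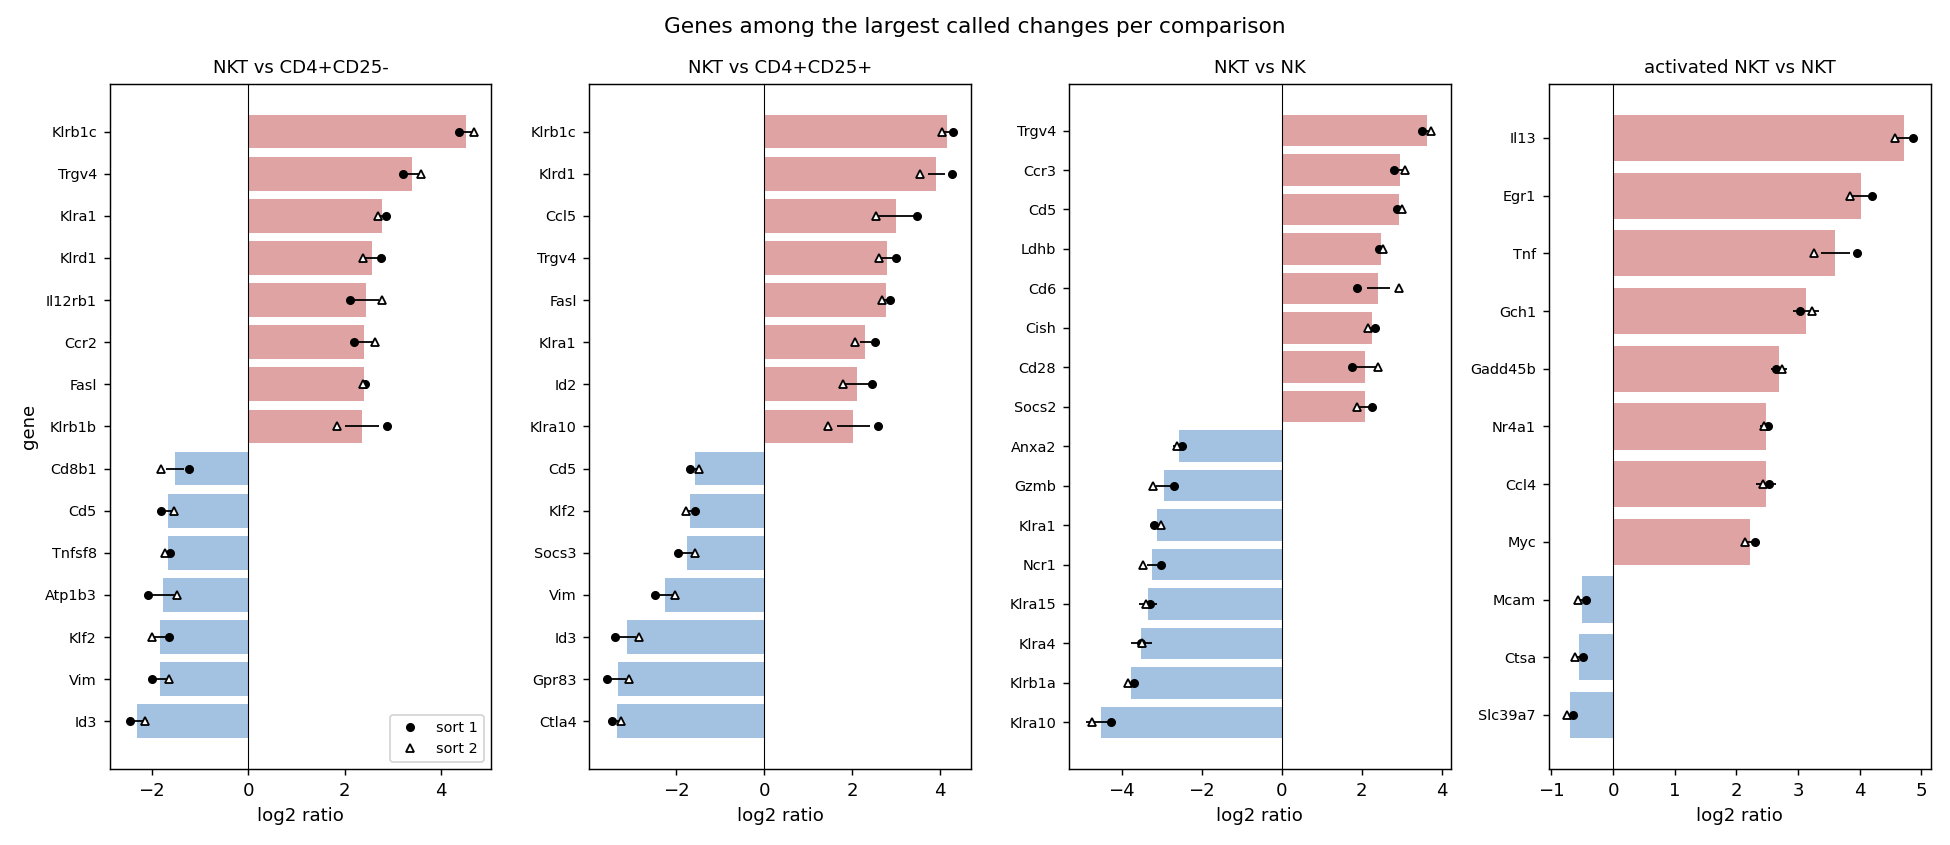
Log2 ratios of genes among those with the largest called differences in each comparison (x axis, log2 ratio; y axis, gene), with bars for the fitted mean, lines for the SE and points for the 2 sorts. Klrb1c stands at 4.53 over CD4+CD25- cells, and Il13 at 4.72 in activated over resting NKT cells.

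The comparison with CD4+CD25+ T cells, the population that contains regulatory T cells, gave 7 of 21 NK receptors and adaptors higher and 6 of 13 regulatory T cell genes lower in NKT cells. Ctla4, an inhibitory receptor, was lower in NKT cells at -3.36 ± 0.10 (SE, n = 2 sorts; adjusted p = 0.000122), and Gpr83, a receptor enriched in regulatory T cells, at -3.34 ± 0.19, with NKT cells well above background on 3 of 4 arrays. Id3 stood at -3.13 ± 0.22. Klrb1c was higher by 4.18 ± 0.14, Klrd1 by 3.92 ± 0.19 and Fasl by 2.77 ± 0.07, the last 2 well above background in CD4+CD25+ cells on 3 of 4 files. The chemokine gene Ccl5 rose by 3.01 ± 0.49, and Id2, which encodes a relative of Id3, by 2.12 ± 0.28.

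Of 13 tested regulatory T cell genes, 6 were lower in NKT cells than in CD4+CD25+ cells, also when adjusted over the list alone, where 1 was higher. They were Ctla4, Gpr83, Tnfrsf4, Capg, Tnfrsf18 and Ikzf2 (list adjusted p = 6.37e-05; adjusted p = 0.133 with an estimated correlation). Tnfrsf4, a co-stimulatory receptor well above background in NKT cells on 3 of 4 arrays, was at -1.51 ± 0.22. Il2ra, which encodes the sorting marker CD25, was at -0.14 ± 0.07 and was not called. Its probe was dim, well above background in NKT cells on 2 and in CD4+CD25+ cells on 3 of 4 files. The value therefore does not tell whether the transcript followed the sort label. Foxp3 was not among the genes measured. Among 11 co-stimulatory and inhibitory receptors, 5 fell and 1 rose, and the counts were equal when adjusted over the list alone (list adjusted p = 0.0157; adjusted p = 0.258 with an estimated correlation). Of 21 NK receptors and adaptors, 7 rose and 1 fell, with equal counts adjusted over the list alone (list adjusted p = 0.000154 over 20 genes; adjusted p = 0.495 with an estimated correlation). Their median was 1.20 in sort 1 and 0.19 in sort 2, beside 1.19 and -0.07 for the myeloid list, of which 0 genes were called. Of 19 Th1 genes, 4 rose, Ccl5, Cxcr3 (1.95 ± 0.07), Il12rb1 and Stat4, and 8 when adjusted over the list alone (list adjusted p = 0.00041 over 18 genes; adjusted p = 0.133 with an estimated correlation).

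Against CD4+CD25+ cells, 348 of 6115 genes passed in limma, 162 higher and 186 lower, and 83 of them differed at least 2-fold. The count and its balance depended on the normalization: median centring gave 1097 calls, 937 higher and 160 lower, and Feature Extraction log ratios gave 196, 116 higher and 80 lower. A replicate block on the sort number gave 199. Scaling the arrays to a common spread left 26 calls, taking the doubtful file as labelled left 0 in limma (76 at an unadjusted p under 0.05), and the comparison's own sort 1 or sort 2 left out gave 38 or 70. Of 36 calls among the named genes, 13 held without either sort, including Ctla4, Gpr83, Klrb1c, Klrd1 and Fasl, but not Ccl5, Id2 or Tnfrsf4.

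The comparison with NK cells asks which features NKT cells do not share with that lineage. NKT cells had lower Klra10 (-4.51 ± 0.38; SE, n = 2 sorts), Klrb1a (-3.77 ± 0.11), which encodes an NKR-P1 receptor, and Ncr1 (-3.24 ± 0.12), which encodes the activating receptor NKp46 and was well above background in NKT cells on 2 of 4 arrays. Gzmb, the granule protease granzyme B, was at -2.96 ± 0.19. Higher in NKT cells were Cd5 (2.94 ± 0.11), a regulator of T cell receptor signalling, Cd6 (2.41 ± 0.29) and the co-stimulatory receptor gene Cd28 (2.08 ± 0.26). Ccr3, a chemokine receptor gene, rose by 2.94 ± 0.14 and Ldhb, a lactate dehydrogenase gene, by 2.48 ± 0.06. Klra10, Klra1, Klra4 and Klra15 are close relatives, and their probes may not tell them apart.

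Of 21 tested NK receptors and adaptors, 15 were lower in NKT cells and 18 when adjusted over the list alone, with a median of -1.72 (list adjusted p = 1.05e-16 over 20 genes; adjusted p = 0.213 with an estimated correlation). The sort medians were -1.83 and -2.09, beside 0.19 and -0.76 for the myeloid list. Of 18 genes of the T cell receptor complex and its signalling, 5 rose, Cd5, Cd6 and Cd28 among them, and 11 rose and 2 fell when adjusted over the list alone (list adjusted p = 2.84e-05; adjusted p = 0.155 with an estimated correlation). Of 15 interferon response genes, 4 rose, led by Tgtp1 (1.75 ± 0.18), and Irf8 (-2.37 ± 0.33) fell; 7 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.000502; adjusted p = 0.185 with an estimated correlation). Of 9 cytotoxic effectors, Gzmb, Serpinb9 (-1.14 ± 0.07; well above background in NKT cells on 2 of 4 arrays) and Gzmc fell, and 5 fell when adjusted over the list alone (list adjusted p = 0.00204; adjusted p = 0.284 with an estimated correlation). Of 11 co-stimulatory and inhibitory receptors, 3 rose and 7 when adjusted over the list alone (list adjusted p = 0.00396; adjusted p = 0.185 with an estimated correlation). Klrb1c was at -0.98 ± 0.20 from 1 sort and was not called. Cd3e (0.13 ± 0.13) and Cd4 (0.12 ± 0.08) were not called, although NK cells lack the proteins they encode, whereas Cd3g, another CD3 chain, was called higher at 2.63 in sort 1 and 1.51 in sort 2.

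Against NK cells, 434 of 6115 genes passed in limma, 162 higher and 272 lower, and 156 of them differed at least 2-fold. Median centring gave 682 calls, 135 higher and 547 lower, and only arrays with NKT cells in Cy3 gave 249. The comparison's own 2 sorts alone gave 81 calls, and leaving out its sort 1 or sort 2 gave 163 or 118. Of 38 calls among the named genes measured in both sorts, 16 held without either sort, including Klra10, Klrb1a, Ncr1, Gzmb, Cd5, Ccr3 and Ldhb, but not Cd6, Cd28, Tgtp1 or Irf8.

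Activation of NKT cells, by a stimulus the labels do not name, raised 9 of 22 immediate early and NF-kB response genes and the cytokine genes Il13, Tnf and Il4. Il13, a type 2 cytokine gene, rose by 4.72 ± 0.12 on the log2 scale (SE, n = 2 sorts; adjusted p = 5.21e-05). Egr1, an early transcription factor gene, rose by 4.02 ± 0.14, Tnf, a pro-inflammatory cytokine gene, by 3.60 ± 0.24 and Gch1, the entry enzyme of tetrahydrobiopterin synthesis, by 3.13 ± 0.21. Gadd45b, Nr4a1, the chemokine gene Ccl4 and Myc rose by 2.69 ± 0.12, 2.48 ± 0.10, 2.48 ± 0.17 and 2.21 ± 0.13. Il4, well above background in resting cells on 2 of the 3 arrays with informative flags, rose by 1.43 ± 0.12. The 3 genes that fell under the same rule were Slc39a7 (-0.70 ± 0.06), Ctsa (-0.55 ± 0.08) and Mcam (-0.51 ± 0.07).

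Of 22 immediate early and NF-kB response genes, 9 rose, and 16 when adjusted over the list alone, with a median of 0.59 (list adjusted p = 5.02e-22 over 21 genes; adjusted p = 0.0458 with an estimated correlation). This was the only list among the 4 direct comparisons whose call held with an estimated correlation. Of 9 heat shock and stress genes, Hsph1 (1.28 ± 0.10), Dnaja1 (1.06 ± 0.15) and Hsp90aa1 rose, and 5 rose when adjusted over the list alone (list adjusted p = 9.2e-05; adjusted p = 0.108 with an estimated correlation). Of 11 co-stimulatory and inhibitory receptors, 3 rose, Tnfsf14 (1.85 ± 0.15), Tnfsf9 (1.04 ± 0.11) and Cd40lg, also 3 when adjusted over the list alone (list adjusted p = 0.00239; adjusted p = 0.144 with an estimated correlation). Of 19 Th1 genes, Tnf, Ccl4 and Ccl3 rose, and 4 when adjusted over the list alone (list adjusted p = 0.0148 over 18 genes, without Tnf; adjusted p = 0.186 with an estimated correlation). Of 11 Th2 genes, Il13 and Il4 rose, with 3 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.0283; adjusted p = 0.408 with an estimated correlation). The myeloid list was lower with 0 of 14 genes called, also 0 adjusted over the list alone, at a median of -1.32 in sort 1 and 0.05 in sort 2 (list adjusted p = 0.0393; adjusted p = 0.696 with an estimated correlation). Il10 (0.06 ± 0.08) and Gata3 (0.06 ± 0.22) were not called. Il17a was not called either (adjusted p = 0.0939). For Il17a, resting NKT cells carried the flag for a signal well above background on 1 of 4 files in each resting comparison. On the activation arrays their only such flag came from a green channel of activated NKT sort 2, where every spot carries it. Channel levels set against the lowest signal well above background gave 1.34-fold for activated over resting cells. On that green channel the measured level entered unchanged, because every spot carries the flag, so this value is not a lower bound.

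On activation, 98 of 6115 genes passed in limma, 71 higher and 27 lower, and the 38 that differed at least 2-fold were all higher. A replicate block on the sort number, which does not turn its sign for activation, gave 56, 48 higher and 8 lower. Scaling between arrays gave 50, 44 higher and 6 lower. The comparison's own 2 sorts alone gave 0 calls in limma (388 at an unadjusted p under 0.05), the log ratios of the image analysis gave 11, all higher, and leaving out sort 1 or sort 2 gave 14 or 25. Of 21 calls among the named genes, 6 held without either sort, namely Il13, Egr1, Gadd45b, Nr4a1, Myc and Il4, while Tnf, Gch1, Ccl4 and the 3 genes that fell did not.

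**Figure D2:**
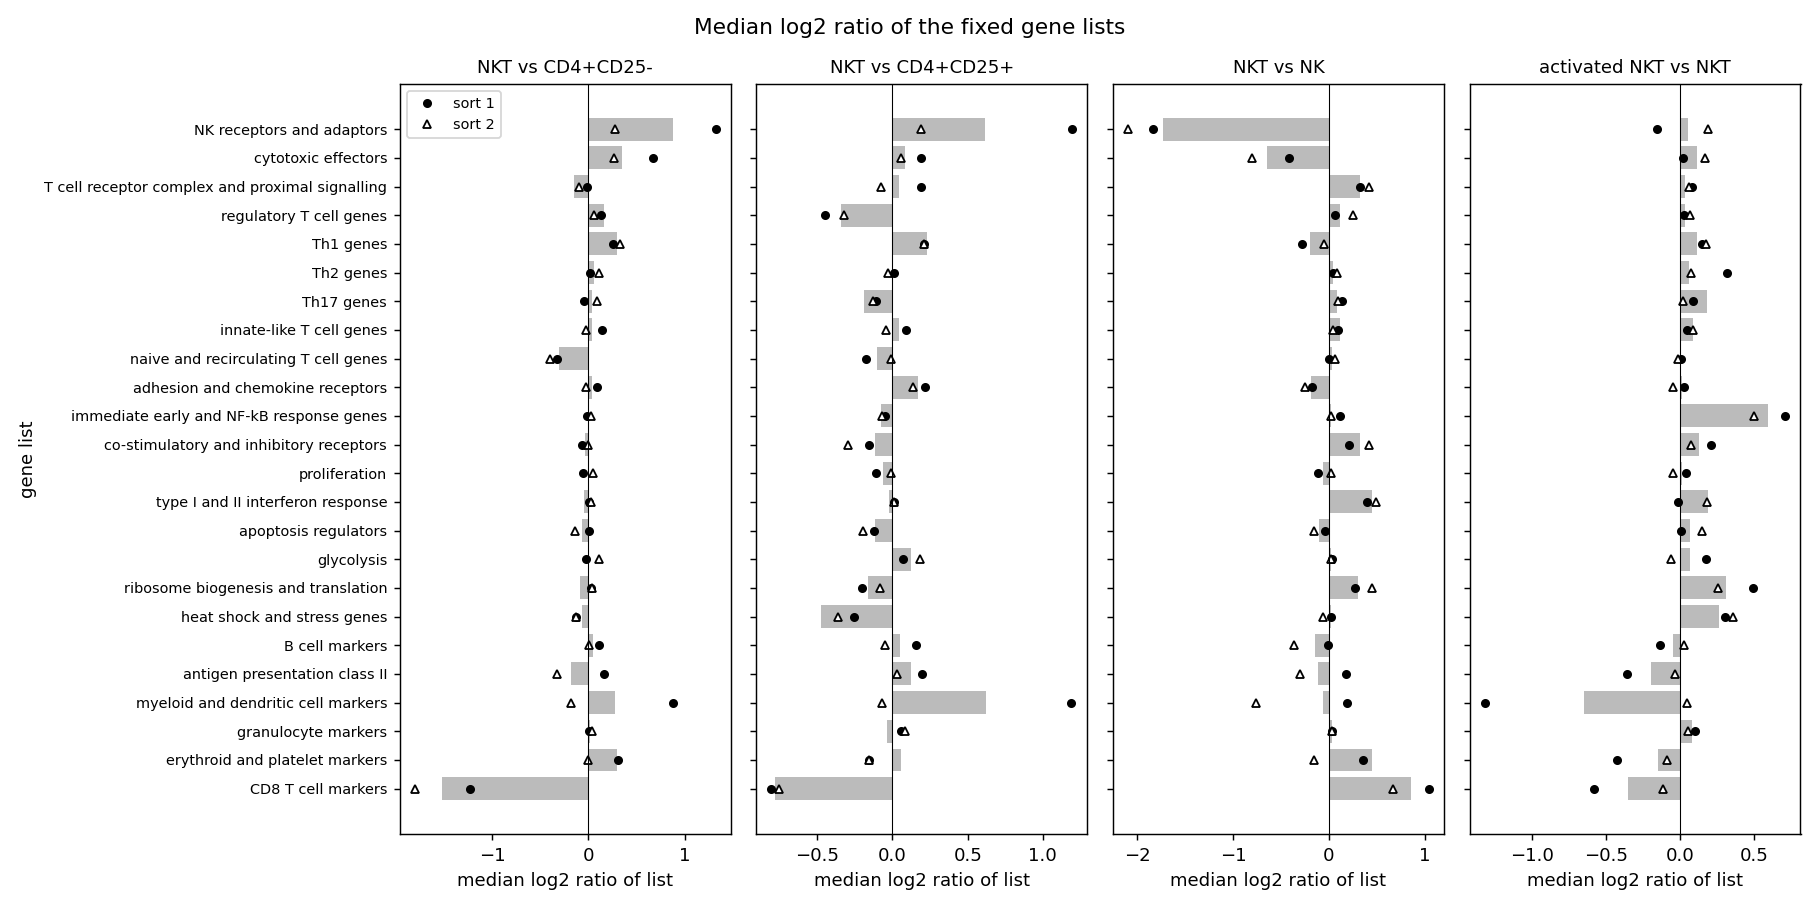
Median log2 ratio of each gene list fixed in advance (x axis, median log2 ratio; y axis, list) in the 4 direct comparisons, with bars for the fitted ratios and points for the 2 sorts. NK receptors and adaptors stand at -1.72 against NK cells, and the immediate early list at 0.59 on activation.

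**Figure D3:**
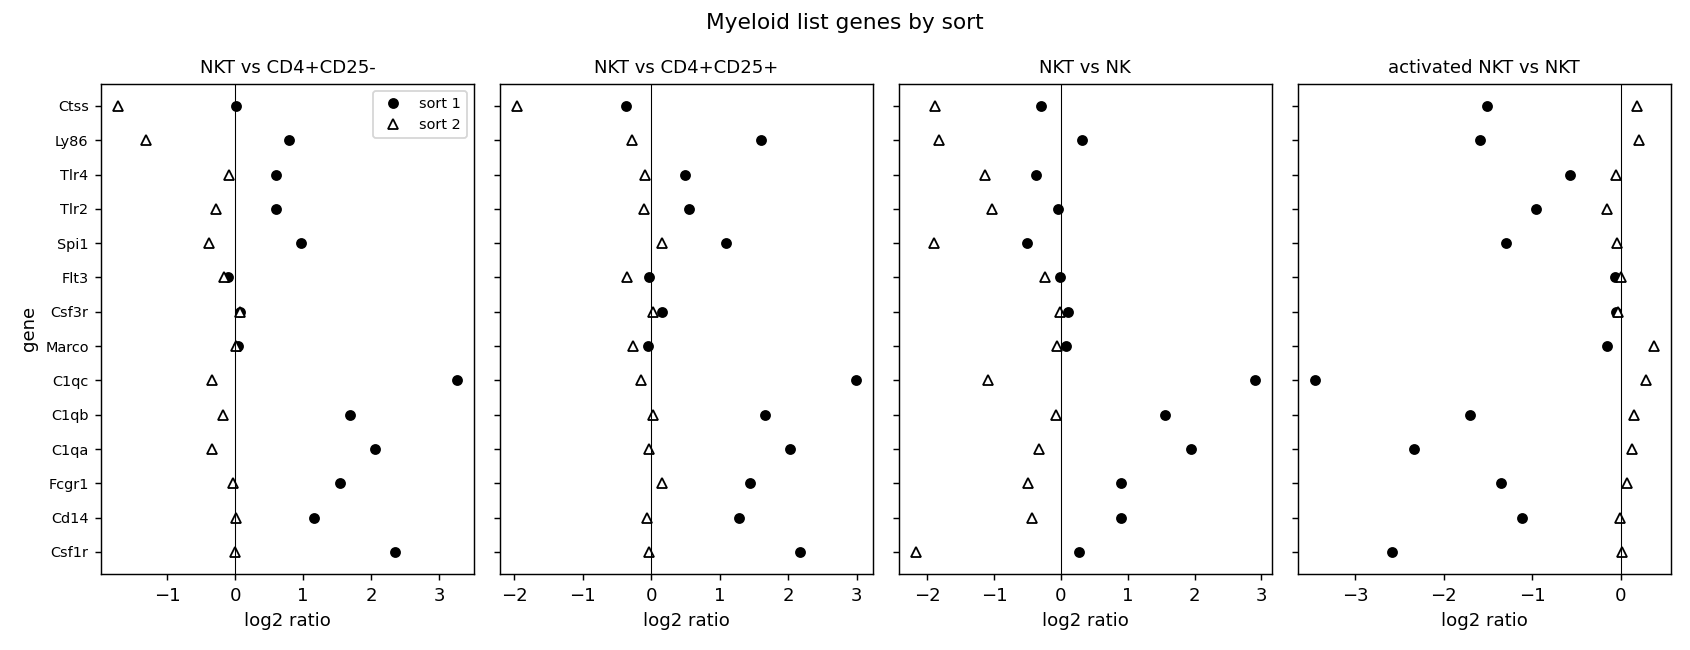
Log2 ratios of the myeloid list genes (x axis, log2 ratio; y axis, gene) in the 4 direct comparisons, with 1 point per sort. The median in activated over resting NKT cells was -1.32 in sort 1 and 0.05 in sort 2.

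CD4+CD25+ and CD4+CD25- cells were never hybridised together, and their difference was taken through the NKT cells. In CD4+CD25+ cells, Cish, a cytokine signalling inhibitor gene, was higher by 2.42 ± 0.12, Gpr83 by 2.33 ± 0.26, Ctla4 by 1.93 ± 0.15 and Tnfrsf18, which encodes the receptor GITR, by 1.86 ± 0.18 (SE, n = 2 sorts per population). Sgk1, a kinase gene, was lower at -1.82 ± 0.12. Il2ra stood at 0.19 ± 0.10 and was not called. Apart from Il2ra, these genes were chosen in this contrast after their values were seen. Of 13 regulatory T cell genes, 3 rose, and 8 when adjusted over the list alone (list adjusted p = 2.77e-14; adjusted p = 0.0232 with an estimated correlation). In limma, 17 of 6115 genes passed, 11 higher and 6 lower, but leaving out any sort of either population gave 0 in limma (232 to 461 at an unadjusted p under 0.05), and scaling between arrays gave 0 (394). Median centring instead gave 349 calls, 20 higher and 329 lower. Sort differences of the 2 comparisons behind this contrast correlated at 0.819. A difference shared by both cancels here, so the SEs of this contrast may be too large. With a sort of either population left out, it no longer cancels.

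Over the mean of the 3 resting partners, Vim (-2.20 ± 0.10), an intermediate filament gene, was lower in NKT cells, and Cxcr3 (1.76 ± 0.04), Ccr3 (2.04 ± 0.08) and Il12rb1 (1.87 ± 0.15) were higher. These genes were chosen from this contrast after their values were seen. In limma, 639 genes passed, 297 higher and 342 lower, against 404 higher and 299 lower with median centring. The fit takes the 3 ratios as independent, although their differences between sorts correlated at 0.819 to 0.897. The SEs and adjusted p-values of this contrast are therefore too small, and the simulated share of false calls did not cover it. Leaving out 1 sort gave 270 to 475, and 62 differed at least 2-fold. In the same direction in all 3 comparisons, 37 genes were called higher and 17 lower. Independent lists would share 0.104 and 0.192 genes, and 20 simulations without effects but with shared NKT cells gave means of 0.1 and 0.05, but with only 1.15 calls in a comparison on average. The top-ranked genes of those simulations, cut to the observed list sizes, shared 74.4 and 88.4. Those cut lists passed no threshold, so neither simulation says how much of the overlap comes from the shared NKT cells, although part of it may. Scaling between arrays left 1 gene in this overlap, and the doubtful file taken as labelled left 0.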

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

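The tests of explanations here were chosen after the results were seen, except that 14 macrophage genes were written down before their shifts between sorts were seen, and the test on raw signals without loess was fixed before its SDs were. Of 117 groups of 4 arrays for named genes, 1 held an array far from the others, where chance alone marks about 5 percent, and none of 18 array measures did. It was Klra1 in NKT over NK cells, where the farthest array took 0.935 of the range between -3.21 and -2.84. CD4+CD25+ was left out of this search, because 1 of its arrays is present as 2 scans.

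The median of the myeloid list was higher in resting NKT cells of sort 1 than of sort 2 in each of the 4 comparisons, although Marco, Csf3r and Flt3 shifted by 0.02, 0.01 and 0.07 against CD4+CD25- cells. C1qc, the most shifted, differed by 3.61 on the log2 scale against CD4+CD25- cells, Csf1r by 2.36 and Ctss, the brightest, by 1.74. An array or scan batch is argued against by myeloid medians of at least 1.07 in each dye orientation of the 3 comparisons with complete dye exchanges. Myeloid cells in the sort 1 NKT preparation may account for the shift, although sorting by tetramer, NK1.1 or CD3 should remove them, and the values leave this open. The 14 macrophage genes, none of them in a list, had a median shift of 0.17 against NK cells, the lowest, and 0.51 with activated cells, the highest. The lowest was under the 0.25 set beforehand as counting against such cells, so the bound as written was not met. It was under by less than the spread of the genes (0.09 to 0.61 between quartiles). Leaving the question open for that spread was not part of what was set beforehand. Lower purity in general stays open too: the median of 12 B cell genes shifted by at most 0.30, but Cd79b by at least 1.46 in every comparison, and the red cell gene Hba-a1 by at least 1.22. In the list that holds Hba-a1, Epor shifted by 0.73 against CD4+CD25- cells and 1.24 with activated cells. Gata1 shifted by -0.13 to 0.16, and Itga2b the other way, by -0.67 to -0.93. How many of these genes NKT cells express was not measured, and no biological explanation was tested.

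The differences between sorts were shared by the comparisons. Across genes, which are not independent replicates, they correlated at 0.819 or more between resting comparisons or, with the sign turned, with activation, which is consistent with resting NKT RNA of each sort used in all comparisons. An array or scan batch is argued against by correlations of at least 0.703 between opposite dye orientations of different comparisons, among the 3 with complete exchanges. Animals and sorting days are not recorded in the labels and stay open.

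The deposited log ratios of activated NKT sort 2 had SDs of 0.319 and 0.384 on the log2 scale, against 0.723 to 0.979 on the other arrays. Background left in by the image analysis may account for this. The test fixed beforehand used raw signals without loess and met both of its bounds: with local background subtracted on all arrays, the SDs were 1.36 and 1.42 (0.854 to 1.71 elsewhere), and the lowest was 1.59 of the lowest elsewhere. With background left in, the raw SDs were also wide, at 0.788 and 0.868 (0.391 to 1.01 elsewhere), so a second test added loess. With loess, the SDs were 0.312 and 0.372 (0.358 to 0.525 elsewhere) with background subtracted and 0.261 and 0.306 (0.281 to 0.43 elsewhere) with it left in. The lowest with subtraction was 0.871 of the lowest elsewhere, under the 0.9 needed. Neither the raw signals nor loess shows that background alone narrowed the deposited values, and which step of the image analysis did stays open.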

How the results depend on the processing

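Tests chosen after the data were seen were those with the doubtful CD4+CD25+ file as labelled, without its dye correction or from the second scan alone, those without the activated NKT sort 2 flags, those with an NKT preparation block or a slide block, and the fit of 15 arrays. Counts are given in the order CD4+CD25-, CD4+CD25+, NK, activation, indirect CD4+CD25+ over CD4+CD25-, mean of 3 partners and 3-way overlap. The main values were 290, 348, 434, 98, 17, 639 and 54. A count not mentioned stayed within 1.5 times its main value, but need not hold the same genes. Error-weighted log ratios with a 2-fold minimum and 1 direction on all arrays gave 307, 282 and 415 genes against CD4+CD25-, CD4+CD25+ and NK cells. Of these, 172, 153 and 264 were main calls. Of 4260 values for named genes, 3534 kept their side of the threshold and direction, 629 lost the call, 52 gained it and 44 uncalled values changed sign. Hsp90ab1 over CD4+CD25+ cells turned to 0.23 with median centring. Of 672 list medians, 614 kept both and 0 turned a call. Of 23 list calls in the 4 direct comparisons, 1 held with an estimated correlation, as did 1 of 6 in the indirect comparison. A lost call does not by itself show that the genes of a list vary together. For the T cell receptor list against NK cells, the estimated correlation was -0.0434, under the preset 0.01. Its unadjusted camera p still rose from 2.58e-06 to 0.00704. Dim probes limit what the arrays can show: without the filter or with the stricter one, all 6 gene counts stayed within 1.5 times.

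Leaving out 1 sort at a time, with the lone sort assumed to vary like the others, gave 42 to 194, 38 to 223, 118 to 336, 14 to 60, 0 to 5, 270 to 475 and 12 to 37. No fit was possible without sort 1 of every comparison, since no residual degrees of freedom remain. With only a comparison's own 2 sorts, 0, 81 and 0 genes passed against CD4+CD25- cells, against NK cells and on activation, and the overlap was 0. At an unadjusted p under 0.05 that limma fit had 650 genes against CD4+CD25- cells and 388 on activation. A 2-fold minimum, which removes calls by construction, gave 91, 83, 156, 38, 62 for the mean and 16 for the overlap.

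Feature Extraction log ratios gave 196 for CD4+CD25+, 11 for activation and 3 for the indirect comparison, and the value table gave 11 for activation and 5 for the indirect one. Median centring gave 1097 for CD4+CD25+, 682 for NK and 349 for the indirect comparison. Scaling between arrays gave 26 for CD4+CD25+ (971 at an unadjusted p under 0.05 against 1162), 50 for activation, 0 for the indirect comparison in limma (394 at an unadjusted p under 0.05) and 1 for the overlap. Only arrays with NKT cells in Cy5 gave 22 for CD4+CD25+, 33 for activation, 0 for the indirect comparison in limma (533 at an unadjusted p under 0.05) and 7 for the overlap, with CD4+CD25+ resting on 1 sort. Only those in Cy3 gave 249 for NK and 10 for the indirect comparison. A trended robust variance gave 225 for CD4+CD25+ and 58 for activation. Apart from these constructions, the cause was not tested.

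The share of higher calls moved by over 10 percentage points with the scaling. For CD4+CD25+ it was 46.6%, against 59.2% with Feature Extraction log ratios, 58.1% in the value table, 85.4% with median centring and 34.6% with scaling. For NK it was 37.3%, against 19.8% with median centring. For activation it was 72.4%, against 100% with Feature Extraction log ratios and in the value table, 85.3% with median centring and 88% with scaling. For the mean it was 46.5%, against 57.5% with median centring, and for the indirect comparison 64.7%, against 40% in the value table and 5.73% with median centring.

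With the doubtful file as labelled, the counts were 52 for CD4+CD25-, 0 for CD4+CD25+ in limma (76 at an unadjusted p under 0.05), 62 for activation, 4 for the indirect comparison, 208 for the mean and 0 for the overlap. The 16 files fitted separately gave 670, 1142, 885, 380, 156, 1406 and 145, but hold 2 scans of 1 array as separate arrays. The 15 arrays with both scans averaged gave 629, 646, 831, 313, 76, 1254 and 116.

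The labels give the same sort numbers to all groups, with 2 numbers too few to establish a pairing. Sort differences correlated at 0.819 to 0.897 between resting comparisons and at -0.831 to -0.911 with activation, where resting NKT cells are the denominator. A replicate block on the sort number gave 189 for CD4+CD25-, 199 for CD4+CD25+, 56 for activation and 2 for the indirect comparison, and it left the other counts within 1.5 times. This block has the same sign in every comparison, although the sort differences run the other way on activation. It therefore cannot follow a shared resting NKT difference in all of them. A block that follows the NKT preparation gave 1859, 2247, 2182, 1434, 683, 2806 and 593. Outside the indirect comparison, where a shared NKT difference cancels, its p-values hold for these preparations alone. Its counts lend the main counts no support. A slide block gave 577, 1071, 833, 11 for the indirect comparison, 3315 for the mean and 119. The correlation it estimated was -0.929. The block joins opposite sorts, CD4+CD25- sort 1 with CD4+CD25+ sort 2, and CD4+CD25+ sort 1 with NK sort 2. Sort differences of these comparisons correlated at 0.819 and 0.897, so joining opposite sorts gives a negative value without any slide effect. The counts of this block lend the main counts no support either. Feature Extraction version as a block gave 644 for CD4+CD25+, 401 for activation, 11 for the indirect comparison and 84 for the overlap, and version is partly tied to sort.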

Other observations

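Further genes were called in the same direction against all 3 partners of resting NKT cells. Bik, which encodes a pro-apoptotic protein, was higher by 1.49 ± 0.08 on the log2 scale over the mean of the partners (SE), Ramp1, a receptor activity modifying protein gene, by 0.96, and Cnr2, the cannabinoid receptor gene of immune cells, by 0.88. Casp4, an inflammatory caspase gene, was lower at -1.07. Each was chosen after its values were seen, and SEs over this mean are too small, because the ratios to the partners share differences between sorts.

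Il17rb, the receptor gene for interleukin 25, was higher by 1.88 ± 0.30 over the mean of the partners (adjusted p = 0.0143), and was also chosen after its values were seen. This SE and adjusted p are too small for the same reason. Against CD4+CD25- cells Il17rb stood at 1.25 in sort 1 and 2.38 in sort 2, and it was not called in any single comparison.

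Cd3e and Cd4 were not called between NKT and NK cells, at 0.13 and 0.12, and the labels put CD3 among the sorting antibodies. Against CD4+CD25- cells they stood at -0.08 and -0.38 and were not called either. Taken through the NKT cells, both probes thus differed little between NK cells and CD4+CD25- T cells as well. Of 2 other CD3 genes, Cd3g stood at 2.63 and 1.51 in the 2 sorts and was called, and Cd3d stood at 3.85 and 2.39 and was not. The cause was not tested.

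Lists of other cell types gave few calls against CD4+CD25- cells. Of 12 B cell markers, Cd72 rose, of 7 granulocyte markers Mmp9 rose, and of 7 class II genes and 4 erythroid and platelet genes none was called. Cd8b1, the measured CD8 marker, was at -1.52 against CD4+CD25- cells, -0.78 against CD4+CD25+ cells, where it was not called, and 0.85 against NK cells.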
